A study of Homo sapiens with 12 samples.

How the data were processed

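Poly(A)-enriched RNA of HepG2 cells, a human hepatoma line that expresses many liver genes, was sequenced in 12 libraries, 3 in each of 4 groups. Per the labels' protocols, cells were pretreated for 1 h with DMSO, the solvent, or with 5 µM A-485, an inhibitor of the acetyltransferase activity of CBP and p300. They were then kept for 24 h in the same compound with or without 30 µg/ml doxycycline, an antibiotic that inhibits translation by mitochondrial ribosomes, and with no other antibiotic. The groups are named DMSO, A-485, Dox, and A-485 and Dox. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries were made for the BGISeq500 sequencer, per the labels' protocols.

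The deposited table holds raw counts, whole numbers of reads per gene, for Ensembl genes in 12 columns. The authors aligned reads with STAR 2.6.0a to GRCh38 and counted them with HTSeq 0.10.0, per the submitters' processing notes. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an antisense neighbour may not be separated. Each gene in the table exceeds 1 CPM (counts scaled to the library total) in at least 2 libraries, which shows a filter before deposit, and genes under that level were not analysed here. The table also has 4 rows that name no gene, and these were left out of library totals and tests. Their shares of all reads in the table were 9.10 to 12.3% for reads assigned to more than 1 gene (ambiguous), 2.96 to 3.76% for reads with several alignments, 3.30 to 4.09% for reads outside annotated genes and 1.80 to 8.93% for unmapped reads. Reads in exons shared by 2 genes fall in the ambiguous share and are missing from both genes' counts. All gene identifiers were found in GENCODE 29 (GRCh38), from which positions, exonic lengths and exon overlaps were taken, and 11812 of them are protein coding. Most of the exon length is shared with another gene in 213 of the genes.

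Gene totals ran from 46600324 to 51773300 counts per library. The median gene had a mean of 1299 counts per library and the lowest a mean of 21.9, so counting error is small for most genes. Reads carry no molecular identifiers, so any interval from counts covers counting error only. The chi-square per degree of freedom between replicates was 1.32 to 3.79 for every pair of libraries in a group except the 2 pairs with Dox replicate 1, at 870 and 888. No pair of libraries differed by as little as sampling noise alone gives, and all 12 were counted as separate.

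Differential expression was tested in R 4.3.3 with edgeR 4.0.16 on the deposited counts: filterByExpr (which removed no gene), TMM scaling, glmQLFit with robust estimation and glmQLFTest, with 1 coefficient per group and all 12 libraries in the fit. Adjusted p-values are Benjamini-Hochberg values over all genes in the table, and a gene is called changed at an adjusted p under 0.05. The standard error of a log2 fold change was derived from the fold change and its F statistic. The 5 contrasts were Dox against DMSO, A-485 against DMSO, A-485 and Dox against Dox, A-485 and Dox against A-485, and the interaction. The interaction is the doxycycline effect with A-485 minus the doxycycline effect without it. Expression levels are CPM on TMM-scaled totals, as mean ± SD over the 3 libraries of a group.

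A total of 31 gene lists, on mitochondrial, stress, metabolic, liver and cell cycle functions, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 31 lists of a contrast, and again with an estimated correlation. Gene counts of a list are given from the adjustment over all genes, and also adjusted over the list alone. For 3 of the 5 contrasts some other splits of the same libraries called as many lists as the real one, so the number of lists is not used as evidence. The member counts and the test with an estimated correlation are given for each list described.

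By the naming rule, a comparison names the 5 genes with the largest rise and the 5 with the largest fall among called genes with a mean log2 CPM of 3 or more and no overlap between the libraries of the 2 groups (for the interaction without the last condition). It also names up to 4 members with the smallest p of each list described, with 1 member going the other way, and 20 fixed genes, of which 19 are in the table; FGF21 is not and was not analysed here. Some genes that the rule or the planned marker list names are not reported here. Which lists to describe was chosen after their values were seen. The direction of genes shared between contrasts that use the same libraries was set against 20 simulations of unchanged groups and 20 with additive effects.

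The fit was checked on simulated counts for the comparison of Dox with DMSO, with 200 changed genes among those of the table. With the spread estimated from all libraries, 53% of the 2-fold and 94% of the 4-fold changes were recovered and 5.77% of calls were false. With the spread estimated without Dox replicate 1 the shares were 100%, 100% and 4.31%. These simulations gave every library the same spread per gene, whereas in the data Dox replicate 1 stood far from the others of its group. The shares, that of false calls among them, therefore need not hold for the real comparison of Dox with DMSO. The alternatives were DESeq2 size factors, library totals alone and upper-quartile factors in place of TMM; no low-count filter and a stricter one; DESeq2 1.42.0 and limma-voom as tools; fits on only the 2 groups compared; the replicate number as a block; leaving out each library in turn; and, for the lists, an estimated correlation and fry. A fit with limma-voom and library quality weights was added after the data were seen. Splits of the libraries were refitted for all 10 splits of 3 against 3, and for 100 drawn relabellings in the interaction. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.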

Results

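RNA-seq counts were compared in HepG2 cells under DMSO, A-485, doxycycline (Dox) and both compounds, with 3 libraries in each of the 4 groups and 46600324 to 51773300 gene counts per library. The 2 by 2 layout asks what doxycycline changes, what inhibition of CBP and p300 changes, and whether the response to this mitochondrial stress differs while CBP and p300 are inhibited.

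Principal component 1 held 75.5% of the variance of log2 CPM and separated the libraries with A-485 from those without it. Component 2 held 16.8% and separated Dox replicate 1 from the other 11 libraries. Across genes, the counts of Dox replicate 1 had Spearman correlations of 0.901 and 0.899 with Dox replicates 2 and 3, which correlated at 0.999 with each other. The biological coefficient of variation was 20.7% with all libraries and 1.52% without Dox replicate 1. That library enters the spread of every gene in all comparisons. The other groups vary far less, so for most genes the pooled spread is narrower than that of the Dox group. SEs and p-values of Dox against DMSO and of A-485 and Dox against Dox are therefore too small in this fit. In the comparisons of 2 groups without Dox they are too large. For this reason the total of each comparison is also given without that library. Counts of list members that it moved by more than 1.5 times are given without it as well. Its log2 deviations from replicates 2 and 3 fell with exonic length, from a median of 1.13 in the first of 10 bins, with the shortest genes, to -0.71 in the last.

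**Figure D1:**
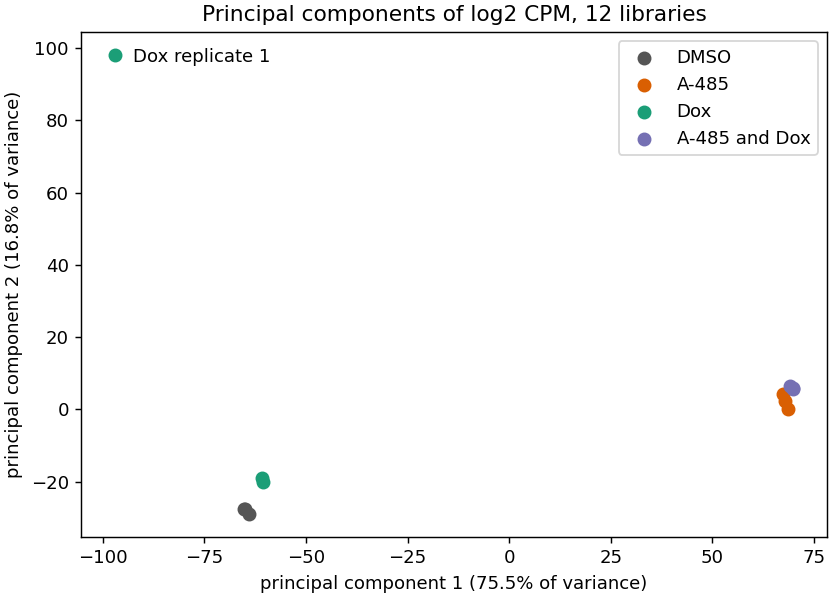
Principal components 1 and 2 of log2 CPM for the 12 libraries, with the share of variance on each axis in percent; each point is 1 library, coloured by group. The 6 libraries with A-485 lie at 67.3 to 69.8 on component 1, and Dox replicate 1 lies at 98.0 on component 2, away from Dox replicates 2 and 3 at -18.9 and -20.0.

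Transcripts of the targets of A-485 were not lower with the inhibitor. CREBBP (ENSG00000005339, chromosome 16, 3725054 to 3880726, GRCh38), which encodes CBP, had 97.6 ± 1.29 CPM (SD, n = 3) in DMSO and 152 ± 2.13 in A-485, a log2 fold change of 0.64 ± 0.23 (SE, edgeR adjusted p = 0.041). EP300 (ENSG00000100393, chromosome 22, 41091786 to 41180079), which encodes p300, had 131 ± 0.832 and 214 ± 7.19 CPM, a change of 0.71 ± 0.34 that did not pass the test (edgeR adjusted p = 0.11) and did pass it without Dox replicate 1, with the same fold change. These are mRNA levels and do not measure the enzymes' activity.

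Doxycycline alone raised genes of the ATF4-driven integrated stress response, which amino acid shortage and other stresses can set off. Of 18 measured members of this list 17 rose and the other did not pass the test (all 18 rose adjusted over the list alone), with a median log2 change of 1.66 (camera adjusted p = 3.2e-22, and adjusted p = 0.00014 with an estimated correlation). ATF4 itself (ENSG00000128272, chromosome 22, 39519695 to 39522685) went from 175 ± 2.91 to 586 ± 22.1 CPM (SD, n = 3), a log2 change of 1.75 ± 0.06 (SE, edgeR adjusted p = 2.3e-07). SESN2, which restrains the growth kinase mTORC1, rose by 2.58 ± 0.08, the transcription factor CEBPB by 1.70 ± 0.06 and the pseudokinase TRIB3 by 2.33 ± 0.17. ASNS, asparagine synthetase, rose by 3.38 ± 0.13, but had only 0.457 CPM in DMSO and shares 44.6% of its exon length with another gene, so part of its reads may be missing from its counts. DDIT3, which encodes CHOP and shares 39.6% of its exon length with MARS, rose by 3.71 ± 0.53 and by 2.67 without Dox replicate 1, and GDF15, a secreted stress hormone, by 0.82 ± 0.20 and by 0.49 without that library.

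Genes that load tRNAs, import amino acids and make serine and one-carbon units rose too. Among 20 cytosolic aminoacyl-tRNA synthetases 12 rose and 8 did not pass the test (13 rose adjusted over the list alone, and 15 rose and 2 fell without Dox replicate 1), among them GARS at 1.92 ± 0.06, AARS at 1.82 ± 0.06 and WARS at 1.69 ± 0.06 (camera adjusted p = 2.4e-13, and adjusted p = 0.00034 with an estimated correlation). Among 10 amino acid transporters 8 rose (9 adjusted over the list alone), including SLC43A1 at 1.53 ± 0.06 and the cystine importer SLC7A11 at 3.12 ± 0.12 (camera adjusted p = 4.8e-10, and adjusted p = 0.012 with an estimated correlation). Of 11 genes of serine, one-carbon and proline synthesis 8 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.9e-05, and adjusted p = 0.0098 with an estimated correlation). The mitochondrial one-carbon enzymes MTHFD2 and MTHFD1L rose by 2.13 ± 0.18 and 1.22 ± 0.06 and the serine enzyme PSAT1 by 1.83 ± 0.13, while the cytosolic SHMT1 fell by 0.35 on the log2 scale. MTHFD2 shares 33.2% of its exon length with SLC4A5.

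Mitochondrial mRNAs had a negative median change with doxycycline, while the mitochondrial rRNA gene MT-RNR1 rose. Of the 13 protein-coding mitochondrial genes 6 fell and 7 did not pass the test, also adjusted over the list alone, with a median of -0.69 (camera adjusted p = 7.1e-07, but adjusted p = 0.33 with an estimated correlation). Without Dox replicate 1 all 13 fell, with a median of -1.71 and a camera adjusted p of 0.0016 with an estimated correlation. MT-CO1 (ENSG00000198804, mitochondrial genome 5904 to 7445), a cytochrome c oxidase subunit, went from 17001 ± 35.6 to 4531 ± 1503 CPM, a log2 change of -1.91 ± 0.20 (SE, edgeR adjusted p = 0.00023). MT-ND5 and MT-ND6 changed by -1.72 ± 0.09 and -2.22 ± 0.24, and MT-ND1 by -0.68 ± 0.31, which did not pass the test (edgeR adjusted p = 0.16) but fell, at -1.28, without Dox replicate 1. The 12S rRNA gene MT-RNR1 (ENSG00000211459, mitochondrial genome 648 to 1601) rose by 3.99 ± 0.42, and by 3.22 without Dox replicate 1. Its level was 1468 ± 3.06 CPM in DMSO, 13707 and 13673 in Dox replicates 2 and 3 and 42360 in Dox replicate 1. Nuclear copies of mitochondrial genes can share reads with them: MTCO1P12, a pseudogene of MT-CO1, changed by -2.08 ± 0.15 alongside it.

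Mitochondrial chaperones and proteases, the usual readout of the mitochondrial unfolded protein response, did not move as a group with doxycycline. Of 15 members 4 rose and 2 fell (4 and 3 adjusted over the list alone, and 7 and 6 without Dox replicate 1), with a median of -0.06 (camera adjusted p = 0.96). The Hsp70 HSPA9 rose by 0.56 ± 0.06 (edgeR adjusted p = 0.00025), its co-chaperone DNAJA3 by 0.52 ± 0.09 and the protease LONP1 by 0.48 ± 0.09, while the protease subunit SPG7 changed by -0.50 ± 0.06. HSPD1, which encodes Hsp60, had 2788 ± 3.96 CPM in DMSO and 2161 ± 368 in Dox, a change of -0.37 ± 0.12 that did not pass the test (edgeR adjusted p = 0.061). HSPE1 and CLPP had changes of 0.51 ± 0.56 and 0.87 ± 0.42, which did not pass the test either (edgeR adjusted p = 0.53 and 0.18). HSPE1, which shares 23.9% of its exon length with HSPD1, fell without Dox replicate 1, at -0.81, and CLPP was at -0.03. TFAM, which packages mitochondrial DNA, was at -0.29 ± 0.13 (edgeR adjusted p = 0.16). HSPD1 and TFAM were called lower without Dox replicate 1, at -0.23 and -0.13.

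Doxycycline lowered cholesterol synthesis, mitosis and cytosolic heat shock genes. Of 22 cholesterol synthesis and uptake genes 14 fell and 8 did not pass the test (16 fell adjusted over the list alone, and 21 without Dox replicate 1), with a median of -0.94 (camera adjusted p = 1.4e-13, and adjusted p = 0.00034 with an estimated correlation). The isoprenoid enzyme IDI1 changed by -1.88 ± 0.09, the sterol enzymes MSMO1 and LSS by -1.54 ± 0.10 and -1.14 ± 0.08 and HMGCS1, at the start of the pathway, by -2.08 ± 0.45. Without Dox replicate 1 HMGCS1 was at -1.64 and IDI1 at -1.78. Of 20 mitosis genes 10 fell (14 adjusted over the list alone, and all 20 without Dox replicate 1), among them the cyclin CCNB1 at -0.70 ± 0.07 and the motor KIF20A at -1.09 ± 0.12 (camera adjusted p = 2.4e-09, and adjusted p = 0.0010 with an estimated correlation). Of 11 cytosolic heat shock genes 6 fell (8 adjusted over the list alone, and 10 without that library), among them HSPA1B at -1.60 ± 0.06 and DNAJA1 at -0.68 ± 0.07 (camera adjusted p = 3.8e-07, and adjusted p = 0.0030 with an estimated correlation). The list of endoplasmic reticulum chaperones and unfolded protein response genes was mixed, with 2 of 17 members up and 4 down (2 and 5 adjusted over the list alone, and 5 and 9 without that library). Its camera adjusted p was 0.0047, but the adjusted p was 0.33 with an estimated correlation, and 0.023 without that library. The chaperone gene CALR changed by -0.90 ± 0.07 and the unfolded protein response gene HERPUD1 by 1.02 ± 0.11. ALB, AFP and MYC changed by -0.45 ± 0.09, -0.41 ± 0.09 and 0.45 ± 0.08, and CDKN1A by 0.09 ± 0.19, which did not pass the test (edgeR adjusted p = 0.76) and fell without Dox replicate 1, at -0.25. HSPA1B shares 36.5% of its exon length with another gene.

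In all, edgeR called 1217 genes higher and 957 lower with doxycycline, of which 293 and 124 changed by more than 2-fold. With Dox replicate 1 left out the counts were 4426 and 4496, with 193 and 146 beyond 2-fold, and 2171 genes were called both ways, all in the same direction. A fit on these 2 groups alone, where the narrower spread of the groups with A-485 does not enter, gave 101 and 43. The largest rises under the naming rule were in NUPR1, a stress-induced chromatin protein (5.65 ± 0.62, and 4.55 without Dox replicate 1), MT-RNR1, the peptide hormone gene ADM2 (3.74 ± 0.19), the activin subunit INHBE (3.73 ± 0.10) and the transcription factor JDP2 (3.73 ± 0.19). The largest falls were in MT-ND6, HMGCS1, MTCO1P12, MT-CO1 and IDI1, each with its value above. Leaving out any 1 of the DMSO libraries lowered the counts to between 619 and 645 higher and between 509 and 517 lower; leaving out Dox replicate 2 or 3 gave 1880 or 2063 higher. Cytosolic ribosomal proteins had a median of 0.73 with camera adjusted p = 0.00024, but adjusted p = 0.82 with an estimated correlation (0.71 without Dox replicate 1). Here edgeR, DESeq2 and limma-voom each called 0 of the 75 members (8 at an unadjusted p under 0.05 in edgeR). Their median was -0.08 without Dox replicate 1, with 3 higher and 47 lower, so the direction turned with that library.

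**Figure D2:**
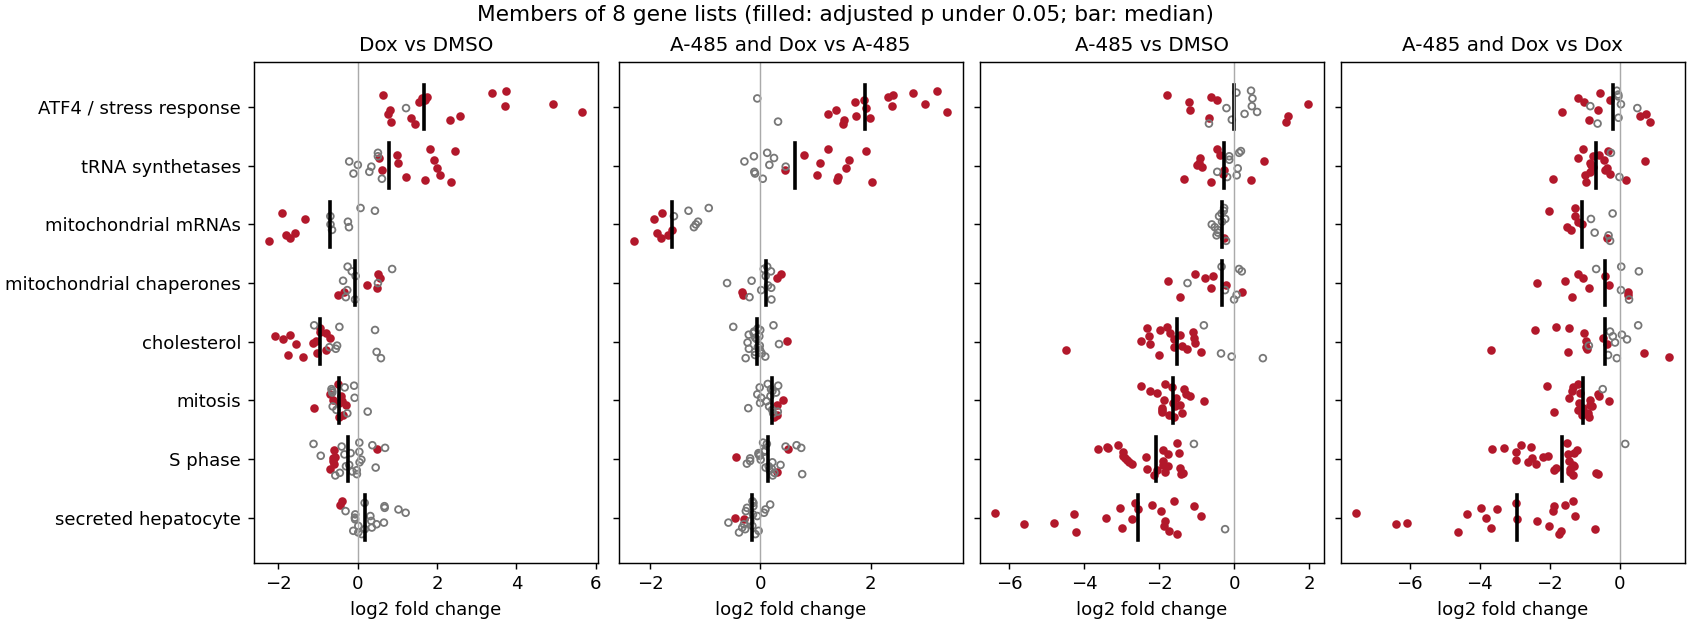
Log2 fold change (x axis) of each measured member of 8 gene lists (rows) in 4 comparisons (panels); filled points passed edgeR at an adjusted p under 0.05 and the bar marks the median. The stress response list has its median at 1.66 with doxycycline alone and 1.90 with doxycycline in A-485-treated cells.

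A-485 alone lowered genes of liver function. Of 21 secreted hepatocyte proteins 20 fell, also adjusted over the list alone, with a median of -2.57 (camera adjusted p = 2.6e-10, but adjusted p = 0.14 with an estimated correlation, and 0.00068 without Dox replicate 1). ALB (ENSG00000163631, chromosome 4, 73397114 to 73421412), serum albumin, went from 21080 ± 184 to 4600 ± 12.4 CPM (SD, n = 3), a log2 change of -2.20 ± 0.09 (SE, edgeR adjusted p = 2.9e-08). The fibrinogen chains FGA and FGB changed by -3.43 ± 0.11 and -2.72 ± 0.07, APOH by -4.28 ± 0.17 and AFP by -1.60 ± 0.09. Of 8 measured acute phase and complement genes 7 fell, also adjusted over the list alone, including ORM1 at -5.59 ± 0.46 and FGL1 at -2.48 ± 0.08 (camera adjusted p = 0.00026, and adjusted p = 0.019 with an estimated correlation). Of 14 hepatocyte transcription factors and nuclear receptors 10 fell and 2 rose, also adjusted over the list alone (10 and 4 without Dox replicate 1): HNF4A changed by -2.93 ± 0.09, CEBPA by -3.78 ± 0.15, the bile acid receptor NR1H4 by -5.42 ± 0.11 and NR1I2 by 0.35 ± 0.10 (camera adjusted p = 0.0014, and adjusted p = 0.023 with an estimated correlation). Markers of other cell types went both ways between DMSO and A-485. The mean CPM of the endothelial markers PECAM1 and TIE1 went from 5.08 to 10.96 and from 0.261 to 2.99. The leukocyte markers CD3D and CD14 went from 0.639 to 1.45 and from 2.50 to 2.19 CPM. The stromal marker PDGFRB went from 4.95 to 0.857 CPM. The planned markers CDH5, VWF and KDR were not analysed here.

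Cell cycle and cholesterol genes were lower with A-485 as well. Of 26 DNA replication and S phase genes 25 fell, also adjusted over the list alone, with a median of -2.09 (camera adjusted p = 4.7e-13, and adjusted p = 0.00080 with an estimated correlation). The replication clamp PCNA and the helicase subunits MCM3 and MCM4 changed by -2.74 ± 0.07, -2.35 ± 0.07 and -2.92 ± 0.09. All 20 mitosis genes fell, also adjusted over the list alone, among them AURKA at -1.83 ± 0.06 and TOP2A at -1.73 ± 0.06 (camera adjusted p = 1.4e-10, and adjusted p = 0.0011 with an estimated correlation). Of 22 cholesterol genes 18 fell, also adjusted over the list alone, with FDPS at -1.70 ± 0.06 (camera adjusted p = 1.1e-06, and adjusted p = 0.0043 with an estimated correlation). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434), a growth regulator, went from 298 ± 3.63 to 20.3 ± 1.12 CPM, a change of -3.87 ± 0.09 (edgeR adjusted p = 1.3e-09).

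The stress genes that doxycycline raised went both ways with A-485. Of the 18 stress response members 3 rose and 6 fell (4 and 7 adjusted over the list alone, and 8 and 9 without Dox replicate 1), with a median of 0.00 (camera adjusted p = 0.67). ATF4 changed by -0.61 ± 0.06 and GDF15 by -1.17 ± 0.20, while TRIB3, ASNS and DDIT3, at -0.06 ± 0.17, 0.06 ± 0.14 and 0.48 ± 0.49, did not pass the test (edgeR adjusted p = 0.79, 0.84 and 0.45). With library totals alone TRIB3 was called higher, at 0.29, and the list median was 0.35. Of 15 mitochondrial chaperones and proteases 7 fell and 1 rose, also adjusted over the list alone (10 and 4 without Dox replicate 1), with a median of -0.33 that library totals alone turned to 0.02 (camera adjusted p = 0.044, but adjusted p = 0.11 with an estimated correlation). HSPD1 changed by -1.76 ± 0.12, TRAP1 by -1.45 ± 0.20, DNAJA3 by -1.06 ± 0.09, HSPA9 by -0.78 ± 0.06 and LONP1 by -0.61 ± 0.09. HSPE1, CLPP, MT-CO1 and MT-ND1 had changes of -1.24 ± 0.56, 0.13 ± 0.42, -0.33 ± 0.19 and -0.59 ± 0.31 and did not pass the test (edgeR adjusted p = 0.09, 0.81, 0.17 and 0.13), while TFAM changed by -0.48 ± 0.13. Without Dox replicate 1 all of the genes of this paragraph but ASNS passed the test.

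The inhibitor called 3547 genes higher and 3656 lower, 1307 and 2021 of them beyond 2-fold; without Dox replicate 1, which enters only the shared spread here, the counts were 6294 and 5900, and a fit on these 2 groups alone gave 6153 and 5976. Under the naming rule the largest rises were in the transcription factors KLF2 (7.43 ± 0.17), EGR3 (5.99 ± 0.30) and EGR2 (5.30 ± 0.22), the protease inhibitor TIMP1 (5.71 ± 0.50) and the water channel AQP3 (5.45 ± 0.11). KLF2 had 9 counts in all in the 3 DMSO libraries against 2119 in A-485, a 178-fold difference with a 95% counting interval of 93.6 to 390. The largest falls were in CPLX2 (1953-fold by counts, interval 1342 to 2964), ACSM2B (603-fold, 317 to 1320), PLA2G2A (517-fold, 323 to 889), AC083841.1 (528-fold, 206 to 1940) and the fatty acid binding protein FABP1 (-8.34 ± 0.36). The scaling sets the balance of directions: 49.2% of calls were higher with TMM and 69.3% with library totals alone, which moved the median of all genes from 0.04 to 0.39. The medians of secreted hepatocyte, acute phase, hepatocyte transcription factor, S phase, mitosis and cholesterol genes stayed below 0 under each scaling tried.

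In cells already under A-485, doxycycline again raised the stress response. Of 18 members 16 rose and 2 did not pass the test (17 rose adjusted over the list alone), with a median of 1.90 (camera adjusted p = 7.2e-38, and adjusted p = 1.8e-05 with an estimated correlation). ATF4 went from 114 ± 1.30 to 570 ± 5.88 CPM (SD, n = 3), a log2 change of 2.32 ± 0.06 (SE, edgeR adjusted p = 6.1e-08), and ATF3, STC2 and CEBPB rose by 2.40 ± 0.10, 1.98 ± 0.07 and 1.87 ± 0.06. TRIB3, ASNS, DDIT3 and GDF15 rose by 1.51 ± 0.17, 2.77 ± 0.13, 2.39 ± 0.50 and 1.37 ± 0.20. Of 20 aminoacyl-tRNA synthetases 11 rose, with GARS at 1.61 ± 0.06 and YARS at 2.02 ± 0.10; adjusted over the list alone 13 rose and 1 fell, and 15 rose and 4 fell without Dox replicate 1 (camera adjusted p = 5.5e-17, and adjusted p = 0.00020 with an estimated correlation). Of 11 serine, one-carbon and proline genes 8 rose and 1 fell, also adjusted over the list alone (8 and 3 without that library), with MTHFD2 at 3.29 ± 0.19, MTHFD1L at 1.01 ± 0.06 and SHMT1 at -0.31 ± 0.06 (camera adjusted p = 2.4e-10, and adjusted p = 0.00096 with an estimated correlation).

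Of the 13 mitochondrial mRNAs 7 fell under A-485 when doxycycline was added (11 adjusted over the list alone, and all 13 without Dox replicate 1), with a median of -1.60 (camera adjusted p = 6.1e-14, but adjusted p = 0.14 with an estimated correlation, and 0.0010 without Dox replicate 1). MT-CO1 changed by -1.78 ± 0.19, MT-ND5 by -1.81 ± 0.09 and MT-ND6 by -2.29 ± 0.24, and MT-ND1, at -1.17 ± 0.31, did not pass the test (edgeR adjusted p = 0.054). MT-RNR1 rose by 3.72 ± 0.42. Of the 22 cholesterol genes 1 rose (also adjusted over the list alone; 4 rose and 8 fell without that library), and the median was -0.06 (camera adjusted p = 0.81). Of 14 immediate early genes 4 rose (9 adjusted over the list alone; 13 rose and 1 fell without that library), among them DUSP1 at 0.91 ± 0.06 and FOSB at 1.20 ± 0.10 (camera adjusted p = 5.6e-10, and adjusted p = 0.0014 with an estimated correlation). HSPA9 and CDKN1A rose by 0.30 ± 0.06 and 0.80 ± 0.19, whereas HSPD1 was at -0.16 ± 0.12, HSPE1 at -0.60 ± 0.56, LONP1 at 0.20 ± 0.08 and CLPP at 0.06 ± 0.42, which did not pass the test (edgeR adjusted p = 0.59, 0.72, 0.24 and 0.99). Without Dox replicate 1 MT-ND1, HSPD1, HSPE1 and LONP1 passed the test with nearly the same fold changes.

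The combined treatment called 505 genes higher and 494 lower than A-485, 120 and 51 of them beyond 2-fold. Without Dox replicate 1, which is in neither group but enters the shared spread, the counts were 4040 and 4872, with 138 and 86 beyond 2-fold. A fit on these 2 groups alone gave 4377 and 4344. Leaving out any 1 of the 6 libraries compared gave 257 to 279 higher and 217 to 236 lower. The largest rises were in INHBE (4.70 ± 0.11), MT-RNR1, NUPR1 (3.38 ± 0.56), MTHFD2 and JDP2 (3.28 ± 0.19). The largest falls were in MT-ND6, the mitochondrial tRNA gene MT-TP (-1.97 ± 0.47), MT-CO3 (-1.92 ± 0.35), MTCO1P12 (-1.91 ± 0.15) and PPP2R2C, with 46 counts in A-485 and 9 in the combined group, a 5.08-fold difference with a 95% counting interval of 2.46 to 11.8.

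**Figure D3:**
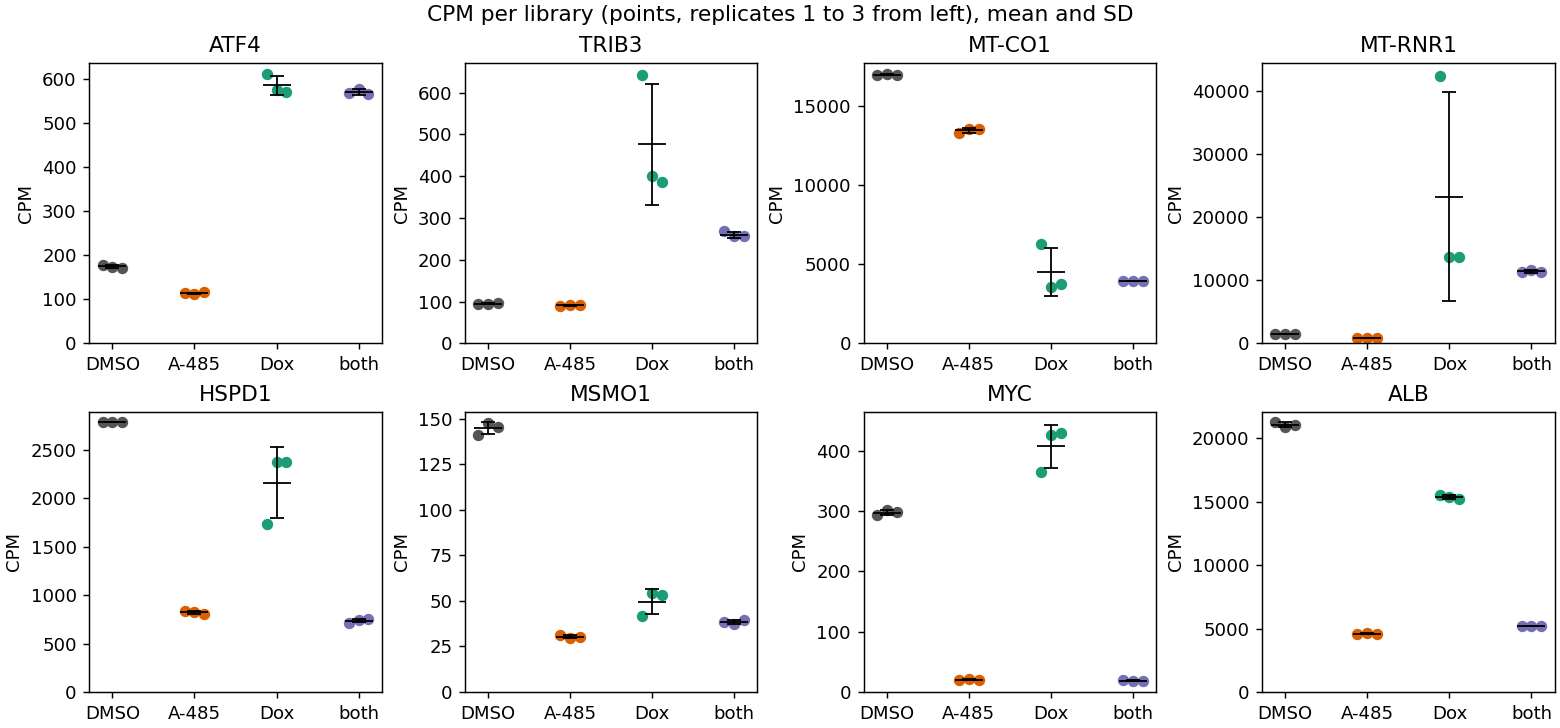
CPM (y axis, from 0) of 8 genes in each library of the 4 groups; points are libraries, with group mean and SD. ATF4 has 586 CPM in Dox and 570 in A-485 and Dox, while MYC falls from 298 CPM in DMSO to 20.3 in A-485; the highest point of MT-RNR1, 42360 CPM, is Dox replicate 1.

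In doxycycline-treated cells, A-485 again lowered hepatocyte and cell cycle genes. All 21 secreted hepatocyte proteins fell, also adjusted over the list alone, with a median of -2.94 (camera adjusted p = 1.1e-09, but adjusted p = 0.18 with an estimated correlation, and 0.0010 without Dox replicate 1), with FGA at -3.82 ± 0.11 and FGB at -2.94 ± 0.07. Of 26 S phase genes 25 fell, also adjusted over the list alone (camera adjusted p = 1.1e-09, and adjusted p = 0.0025 with an estimated correlation), with PCNA at -2.39 ± 0.07, and 19 of 20 mitosis genes fell (20 adjusted over the list alone), with AURKA at -1.20 ± 0.05 (camera adjusted p = 2.7e-06, and adjusted p = 0.0077 with an estimated correlation). Of 14 immediate early genes 9 rose and 2 fell, also adjusted over the list alone: EGR2 and EGR3 rose by 5.87 ± 0.22 and 6.51 ± 0.30, and MYC changed by -4.47 ± 0.09 (camera adjusted p = 0.00049, and adjusted p = 0.023 with an estimated correlation).

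With both compounds, ATF4 did not differ detectably from doxycycline alone, at 570 against 586 CPM, a log2 difference of -0.04 ± 0.06 (edgeR adjusted p = 0.60); with library totals alone it was called higher, at 0.38. Of the 18 stress response members 3 were higher and 7 lower, also adjusted over the list alone (7 and 10 without Dox replicate 1; camera adjusted p = 0.57). VLDLR and SESN2 were at 0.87 ± 0.10 and 0.59 ± 0.08, CEBPG at -1.03 ± 0.14, TRIB3 at -0.87 ± 0.17, ASNS at -0.55 ± 0.11 and GDF15 at -0.62 ± 0.20 (-0.28 without Dox replicate 1). DDIT3, at -0.84 ± 0.48, did not pass the test (edgeR adjusted p = 0.15) and was called higher, at 0.20, without Dox replicate 1. HSPD1 changed by -1.55 ± 0.12, HSPA9 by -1.04 ± 0.06, LONP1 by -0.89 ± 0.09 and HSPE1 by -2.36 ± 0.58 (-1.04 without Dox replicate 1). CREBBP and EP300 transcripts were higher, by 0.84 ± 0.23 and 0.96 ± 0.35, or 0.56 and 0.58 without Dox replicate 1.

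This comparison called 3657 genes higher and 4450 lower, 1309 and 2537 of them beyond 2-fold, and 5972 and 5897 without Dox replicate 1. A fit on the 2 groups alone gave 2125 and 2874. The largest rises were in KLF2 (176-fold by counts, interval 121 to 266), EGR3, EGR2, EGR1 (5.36 ± 0.39) and AQP3 (5.03 ± 0.11). The largest falls were in CPLX2 (1953-fold by counts, interval 1333 to 2990), ACSM2B (1735-fold, 593 to 8419, from 3 counts in the combined group), AC012065.3 (567-fold, 299 to 1242; a log2 change of -9.27, and -8.09 without Dox replicate 1), HS1BP3-IT1 (329-fold, 208 to 556) and FABP1 (-8.15 ± 0.36). The share of calls that were higher was 45.1% with TMM and 67.1% with library totals alone.

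The interaction test asked directly whether the doxycycline effect differed with A-485. Cholesterol genes were lowered by doxycycline in the absence of A-485 more than in its presence: of 22 members 7 had a called interaction, all positive (14 adjusted over the list alone, and 19 positive and 2 negative without Dox replicate 1), with a median of 0.86 (camera adjusted p = 2.9e-16, and adjusted p = 0.00021 with an estimated correlation). MSMO1 (ENSG00000052802, chromosome 4, 165327623 to 165343160) went from 145 ± 3.22 to 49.6 ± 6.83 CPM with doxycycline alone, and from 30.4 ± 0.766 to 38.4 ± 1.10 CPM with doxycycline under A-485 (SD, n = 3). Its interaction was 1.88 ± 0.14 on the log2 scale (SE, edgeR adjusted p = 0.00017), with IDI1 at 1.82 ± 0.13. IDI1 shares 14.8% of its exon length with IDI2-AS1. Mitosis genes had positive interactions too, with 8 of 20 called, all positive (15 adjusted over the list alone, and all 20 without that library). Their median was 0.64, with TPX2 at 0.72 ± 0.08, CDK1 at 1.03 ± 0.12 and AURKA at 0.63 ± 0.08 (camera adjusted p = 2.5e-16, and adjusted p = 0.00021 with an estimated correlation). With doxycycline under A-485, however, mitosis genes went both ways. CDK1 had 34.8 to 36.2 CPM in A-485 and 44.9 to 48.4 in A-485 and Dox, whereas KIF20A had 29.4 to 29.9 and 24.6 to 26 CPM.

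Immediate early genes had 6 positive and 1 negative interaction among 14 (7 and 1 adjusted over the list alone, and 9 and 1 without Dox replicate 1): DUSP1, a MAP kinase phosphatase, at 1.48 ± 0.09, FOSB at 1.45 ± 0.15 and ATF3 at 1.75 ± 0.14 against MYC at -0.59 ± 0.12 (camera adjusted p = 1.3e-08, and adjusted p = 0.0026 with an estimated correlation). Hypoxia-inducible genes had 4 positive of 15 (5 adjusted over the list alone, and 14 without that library), among them the vasodilator peptide ADM at 1.41 ± 0.08 and NDRG1 at 0.74 ± 0.12 (camera adjusted p = 8.3e-09, and adjusted p = 0.0026 with an estimated correlation). For the stress response list the interaction had no common direction, with 3 positive and 1 negative of 18 (3 and 7 adjusted over the list alone, and 7 and 10 without that library; camera adjusted p = 0.97). ATF3, STC2 and ATF4 were positive, at 1.75 ± 0.14, 0.64 ± 0.09 and 0.58 ± 0.09, and SESN2 negative, at -0.84 ± 0.11. TRIB3, ASNS, DDIT3 and GDF15 were at -0.81 ± 0.23, -0.61 ± 0.18, -1.32 ± 0.69 and 0.55 ± 0.28 and did not pass the test (edgeR adjusted p = 0.12, 0.19, 0.40 and 0.38), and without Dox replicate 1 all 4 passed it, at -0.54, -0.61, -0.28 and 0.89. Among aminoacyl-tRNA synthetases 1 of 20 passed, AARS at -0.60 ± 0.08 (6 negative adjusted over the list alone, and 3 positive and 17 negative without that library; camera adjusted p = 0.0014, and adjusted p = 0.024 with an estimated correlation).

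Among called genes with a mean log2 CPM of 3 or more, the 4 largest positive interactions were in MSMO1, ANKRD1 (1.85 ± 0.15), IDI1 and ATF3, and the largest negative ones in TXNIP (-2.75 ± 0.24), AKNA (-2.02 ± 0.21), DEPP1 (-1.98 ± 0.22), IL1RN (-1.73 ± 0.31) and ARRDC4 (-1.70 ± 0.34). TXNIP, which encodes a redox and glucose regulator, went from 27.4 ± 0.18 to 64.1 ± 17.5 CPM with doxycycline alone and from 148 ± 3.07 to 51.7 ± 0.69 CPM with doxycycline under A-485. DEPP1 shares 23.3% of its exon length with RASSF4. ALB had an interaction of 0.63 ± 0.12, and MT-CO1, MT-ND1, HSPD1, HSPE1, HSPA9, LONP1, CLPP, TFAM, AFP, CDKN1A, CREBBP and EP300 did not pass the test, with edgeR adjusted p of 0.15 or more. All of these but HSPE1, CLPP and TFAM passed it without Dox replicate 1, where CREBBP, EP300 and MT-ND1 changed sign, to -0.08, -0.13 and 0.11. HSPE1 and CLPP changed sign too, to 0.20 and 0.09.

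In total 169 genes had a positive and 179 a negative interaction, 49 and 39 of them beyond 2-fold. The fit without Dox replicate 1 gave 2939 and 3597, with 119 and 81 beyond 2-fold, and all 348 were called again with the same sign. Leaving out any 1 of the DMSO, A-485 or combined libraries gave 62 to 72 positive and 60 to 71 negative genes. The share of positive calls was 48.6% with TMM and 33.3% with library totals alone. Among genes that doxycycline raised, 138 had a negative interaction and 12 a positive one; among genes that it lowered, 111 had a positive interaction and 2 a negative one. When Dox replicate 1 was left out these counts were 2343, 304, 2091 and 440. The doxycycline contrast enters the interaction with the opposite sign, which by itself favours opposite signs. The 20 simulations with additive effects had too few called interactions in these classes, at most 2, to give an expected split.

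**Figure D4:**
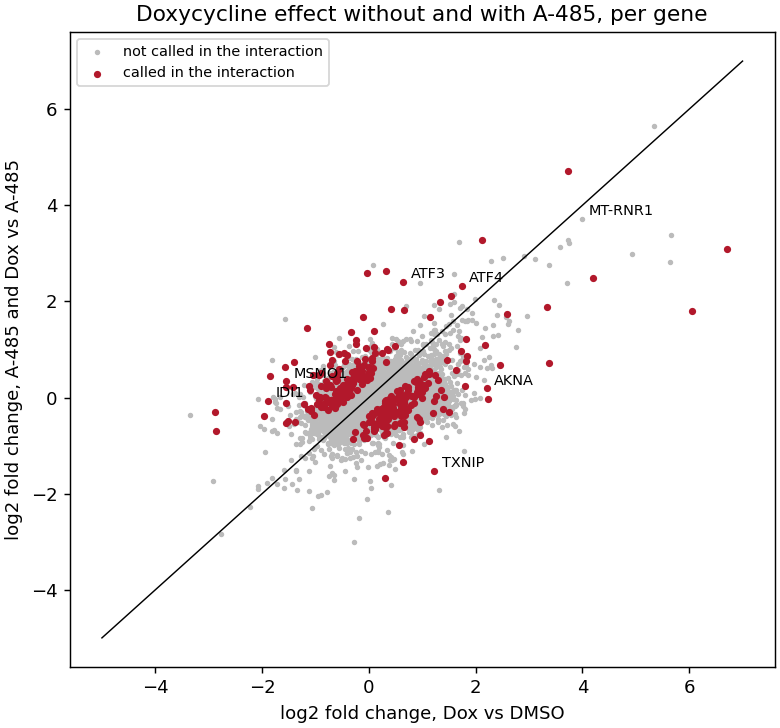
Log2 fold change of each gene with doxycycline alone (x axis) and with doxycycline under A-485 (y axis); red points passed the interaction test, grey points did not, and the line marks equal effects. MSMO1 and IDI1 lie above the line and TXNIP and AKNA below it.

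Across genes, which are not independent replicates, the doxycycline effects without and with A-485 had a Pearson correlation of 0.396 (Spearman 0.264), and simulations in which both effects add gave 0.663. The values were 0.600 and 0.911 without Dox replicate 1. Of the genes called in either of these comparisons, 79.2% had the same sign (95.6% in the additive simulations), and 73.0% without Dox replicate 1 (96.9% simulated). The A-485 effects without and with doxycycline correlated at 0.919 (simulated 0.955), with the same sign for 95.6% of the genes called in either (97.9% simulated). These simulations gave every library the same spread per gene, whereas Dox replicate 1 stood far from the others of its group. With all libraries the gaps therefore do not measure a departure from additive effects. The values without Dox replicate 1 are free of that library. The effects of doxycycline alone and of A-485 alone share the DMSO libraries. Their correlation of 0.061 was below the mean of simulated groups without effect. Such groups share only noise in the DMSO libraries, so that mean is no measure for real effects. The covariance was 0.0399 against 0.0343 simulated, and 0.0755 against 0.00368 without Dox replicate 1. In the first pair every simulated library, DMSO included, had the spread that Dox replicate 1 widened, so 0.0343 overstates the shared noise. Both compounds raised 491 genes and lowered 535, where independent lists of these sizes would share 319.5 and 259; 338 genes were higher with doxycycline and lower with A-485 (329 for independent lists) and 229 the reverse (251). The additive simulations, which share the DMSO libraries too, gave means of 111, 191, 158 and 88 in this order. Without Dox replicate 1 the counts were 2349, 2632, 1649 and 1518, against 2062, 1963, 1933 and 2094 for independent lists and 1647, 2482, 1618 and 1681 in those simulations. The numbers of genes called in the simulations were not kept and may differ from the observed ones, so the simulated means do not measure an excess. Part of the excess over independent lists may come from the shared DMSO libraries.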

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

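Planned tests here were the interaction, the splits of the libraries, the length and GC trend set against the other 11 libraries, the strength of the response and the removal of the mitochondrial rRNA genes with TMM scaling; the other tests of the 3 patterns below were chosen only after the result was seen. A test of the difference between the doxycycline effects with and without A-485 singled out 169 genes with a positive and 179 with a negative interaction. Named genes with a positive interaction were MSMO1 (1.88), ANKRD1 (1.85), IDI1 (1.82), ATF3 (1.75), DUSP1 (1.48), FOSB (1.45), ADM (1.41), CDK1 (1.03), NDRG1 (0.74), TPX2 (0.72), STC2 (0.64), AURKA (0.63), ALB (0.63) and ATF4 (0.58). Those with a negative one were TXNIP (-2.75), AKNA (-2.02), DEPP1 (-1.98), IL1RN (-1.73), ARRDC4 (-1.70), SESN2 (-0.84), AARS (-0.60) and MYC (-0.59).

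Gene lists whose camera test passed in the interaction had median log2 values of 0.86 for cholesterol synthesis, 0.64 for mitosis, 0.60 for immediate early genes, 0.46 for amino acid transporters, 0.39 for S phase, 0.37 for endoplasmic reticulum chaperones, 0.35 for hypoxia-inducible genes and 0.24 for fatty acid synthesis. Negative medians were -0.76 for cytosolic ribosomal proteins, -0.65 for oxidative phosphorylation subunits, -0.30 for aminoacyl-tRNA synthetases and -0.24 for lysosome and autophagy genes. With an estimated correlation 6 of these 12 lists passed, those of cholesterol, mitosis, immediate early, S phase, hypoxia-inducible and aminoacyl-tRNA synthetase genes. The medians of ribosomal proteins and oxidative phosphorylation turned to 0.04 and 0.08 without Dox replicate 1. Among reads not used in the comparisons, the share outside annotated genes was above that of DMSO (3.39%) with A-485 (3.95%), doxycycline (3.64%) and both (4.07%), and the ambiguous share was 12.3% in Dox replicate 1. Unmapped reads count in these shares and, at 7.17% and 8.93%, lower those of DMSO replicates 1 and 2. In DMSO replicate 3, with 1.86% unmapped, 3.53% of reads lay outside annotated genes. The Dox replicates 2 and 3 had 3.55% and 3.60%, and Dox replicate 1 had 3.77%, so the difference with doxycycline was small outside that library.

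Dox replicate 1 stood apart from Dox replicates 2 and 3. Loss of signal with transcript length goes with its deviations, which had a Spearman rho of -0.445 with exonic length, where the highest absolute value was 0.270 outside the Dox group and 0.439 in Dox replicates 2 and 3, whose deviations contain Dox replicate 1. A rho of 0.431 with GC content, against at most 0.325 outside the Dox group, is about as large, so length and GC are not separated. This trend as the whole cause was left open by the planned bound (SD of 0.930 after length and GC are removed, against 0.482 in the other Dox libraries), but argued against by the later bound, 0.129 in the 9 libraries of the other groups. The correlation of the deviations of Dox replicate 1 with the doxycycline effect under A-485 was -0.0918. This does not decide on a stronger or weaker response, since deviations with an SD of 1.10 over genes would lower any such correlation. A library of the A-485 and Dox group is argued against by 95.2% of 21 secreted hepatocyte genes nearer to Dox replicates 2 and 3 than to that group. A DMSO library is argued against by 88.9% of 18 stress response genes nearer to those replicates than to DMSO (95% interval 65.3 to 98.6%), with a median 1.38 above DMSO after the trend is removed, although only 30.8% of 13 mitochondrial mRNAs were. An A-485 library is argued against by a component 1 of -96.9, where the libraries with A-485 lie at 67.3 to 69.8; the share of secreted hepatocyte genes nearer to Dox replicates 2 and 3 than to A-485, 90.5% (69.6 to 98.8%), missed a first bound of 75%. A library from outside the 4 groups cannot be told apart, since the share over the 52 members of the 3 lists, 76.9% (63.2 to 87.5%), compares with DMSO and A-485 and Dox only. The rules for these label tests were set or changed after values were seen. The strength of the response was the only biological explanation tested.

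Cholesterol genes had a median change of -0.94 with doxycycline alone and -0.06 with doxycycline under A-485. This difference had a median interaction of 0.856. Dox replicate 1 as its cause is argued against by 0.943 without it, the scaling by a lowest median of 0.845, and counts near the floor by a median of 1876 counts per A-485 library. What stays open is that both treatments may lower these genes through overlapping steps: the combined effect against DMSO was -1.66, between the larger single effect of -1.53 and the sum of -2.47. Any effect that is less than additive would give such a value, so this cannot be told apart from a dependence of the doxycycline effect on CBP and p300.

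With doxycycline 6 of 13 mitochondrial mRNAs were called lower and the rest did not pass the test, while the rRNA gene MT-RNR1 was higher. As a list the mRNAs did not pass camera with an estimated correlation (adjusted p = 0.33), except without Dox replicate 1. Counts of rRNA taking up the library, as the whole cause, are argued against with library totals as the scaling, where the median mRNA change went only from -0.902 to -0.813 when both rRNA genes were left out. With TMM, which trims such genes, it stayed at -0.69, which decides nothing. Dox replicate 1 is argued against by -1.71 without it. MT-RNR2, named after its values were seen, was at 1.84 ± 0.36, and 1.16 without Dox replicate 1. A change in poly(A) capture of the rRNA may also raise MT-RNR1, by 3.99 here, and cannot be told apart from more rRNA, since no library was made without poly(A) enrichment.

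Splits of the 6 libraries in each comparison of 2 groups number 10 with the real one, too few for a share under 0.05. The real split, 1 of 10, called 2174, 7203, 8107 and 999 genes for Dox against DMSO, A-485 against DMSO, A-485 and Dox against Dox and A-485 and Dox against A-485. In each, the highest other split called 0 by edgeR. Every other split puts libraries of both treatments in the same group and so widens the spread. Few calls there were thus fixed in advance and decide nothing. For the gene lists the real splits called 15, 18, 17 and 10 and the highest others 11, 18, 13 and 12, with 1, 3, 1 and 10 of 10 splits as high, the real one included. For the interaction 2 of 100 relabellings, the real one included, called as many genes as the real 348. The highest, 2447, exchanged A-485 with A-485 and Dox in all 6 libraries, a structure of the samples, and the highest of the rest was 59. This count does not exclude chance, since the other relabellings put libraries with and without doxycycline in the same group. Such mixing widens the spread and by itself lowers the number of calls. The 12 lists called were reached in 22 of 100 relabellings, with a highest of 16. The 249 doxycycline-changed genes with the opposite interaction sign are among the 348, and this number was reached in 2 of 100 with a highest of 1673. Relabellings with at most 59 calls could not reach it, so this says nothing about an excess of opposite signs.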

How the results depend on the processing

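The quality weights were chosen only after the result was seen, and all other settings were planned. DESeq2 size factors, upper-quartile factors, limma-voom and both low-count filters reversed no named gene and moved no count of called genes by over 1.5 times; DESeq2 size factors, upper-quartile factors and the filters left all 226 named results on the same side of the test, and limma-voom 224. The fit without a low-count filter repeats the main fit, whose filter removed no gene, so its agreement was fixed in advance. Where a cause is not given, the cause was not tested.

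With library totals alone 621 genes were lower with doxycycline, 5502 higher with A-485, 5686 higher and 2793 lower with A-485 in doxycycline-treated cells, and 88 had a positive interaction. Genes raised by doxycycline with a positive interaction numbered 3, lowered ones with a positive 61 and with a negative interaction 0, and 272 were lower with both compounds. TRIB3 turned to 0.29 with A-485, and ATF4 and MT-CO1 to 0.38 and 0.26 with A-485 in doxycycline-treated cells. These factors move the median effect of A-485 from 0.04 to 0.39. DESeq2 called 1577 lower with doxycycline, 870 higher and 979 lower with doxycycline under A-485, and interactions of 542 and 535. Its overlaps of doxycycline-changed genes were 373 raised with a negative and 21 with a positive interaction, and 389 lowered with a positive and 15 with a negative one. It found 840 genes lower with both, 534 higher with doxycycline and lower with A-485, and 401 the reverse.

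With the replicate block the comparison of both compounds with A-485 gave 327 higher and 299 lower genes and the interaction 70 and 68, with overlaps of 56, 5, 49 and 0; no gene list changed its call. The numbers do not pair the libraries: the 18 same-numbered pairs correlated from -0.25 to 0.11, with 1 above 0.1, and 1 of 12 libraries correlated best with its own number.

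Fits on only the 2 groups compared gave 101 higher and 43 lower genes with doxycycline, 6153 and 5976 with A-485, 2125 and 2874 with A-485 in doxycycline-treated cells and 4377 and 4344 with doxycycline under A-485, since Dox replicate 1 then sets the spread only where it is compared. Limma-voom with quality weights gave 4516 and 4564, 6344 and 5935, 5989 higher, and 4105 and 4995 genes in that order, and interactions of 3017 and 3787. Its overlaps were 2457, 313, 2136 and 464, the correlations 0.598 for the doxycycline effects and 0.153 for the effects of the 2 compounds, and the shared calls 2434, 2656, 1670 and 1570. With it EP300 was at 0.23, HSPE1 at -0.81 and CDKN1A at -0.24 with doxycycline, DDIT3 at 0.20, CLPP at 0.22 and MT-CO1 at 0.10 with A-485 in doxycycline-treated cells, and CREBBP at -0.083 and EP300 at -0.14 in the interaction.

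Leaving out each library gave 619 to 4426 higher and 509 to 4496 lower genes with doxycycline, 2952 to 6294 and 3172 to 5900 with A-485, 3071 to 5972 higher with A-485 in doxycycline-treated cells, 257 to 4040 and 217 to 4872 with doxycycline under A-485, and interactions of 62 to 2939 and 60 to 3597. The overlaps ran from 51 to 2343, 5 to 304, 45 to 2091 and 0 to 440, the correlations from 0.3004 to 0.600 and 0.0298 to 0.148, and the shared calls from 237 to 2349, 290 to 2632, 172 to 1649 and 110 to 1518. The highest of each came without Dox replicate 1. For doxycycline EP300 ran from -0.39 to 0.23, HSPE1 from -0.81 to 0.90 and CDKN1A from -0.25 to 0.23. For A-485 in doxycycline-treated cells DDIT3 ran from -1.18 to 0.20, CLPP from -0.98 to 0.22 and MT-CO1 from -0.35 to 0.10. In the interaction CREBBP ran from -0.082 to 0.37, EP300 from -0.13 to 0.49 and MT-ND1 from -0.73 to 0.11. In each of these genes the direction turned only without Dox replicate 1.

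Without Dox replicate 1 the direction of some lists turned too. The camera adjusted p over all libraries left out ran from 2.8e-07 to 0.15 for oxidative phosphorylation, 0.00046 to 0.97 for secreted hepatocyte proteins and 1.4e-07 to 0.049 for ribosomal proteins with doxycycline, 0.0017 to 0.95 for oxidative phosphorylation with A-485 in doxycycline-treated cells, and 5.1e-06 to 0.031 for oxidative phosphorylation in the interaction. For cytosolic ribosomal proteins in the interaction it ran from 7.4e-08 to 0.092. With an estimated correlation none of these 6 results passed without Dox replicate 1, with adjusted p of 0.13 or more. With an estimated correlation 8, 8, 10 and 6 lists were called for doxycycline, A-485, A-485 in doxycycline-treated cells and the interaction. Fry called 23, 28, 27 and, for doxycycline under A-485, 17 lists, and its mixed form 24, 29, 29 and 23; with fry, heat shock genes had an adjusted p of 0.0051 in the other direction for A-485 in doxycycline-treated cells.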

Other observations

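Of 20 genes of lysosomes and autophagy 10 were higher and 3 lower with A-485 (11 and 3 adjusted over the list alone, and 13 and 7 without Dox replicate 1; camera adjusted p = 0.025, but adjusted p = 0.078 with an estimated correlation, and 0.079 without that library). GABARAPL1 and MAP1LC3B, whose products coat autophagosomes, rose by 1.90 ± 0.07 and 1.22 ± 0.06 on the log2 scale (SE, n = 3), and GLA, a lysosomal galactosidase, changed by -1.04 ± 0.22. Of 24 acetyltransferases, deacetylases and bromodomain proteins 10 rose and 5 fell (10 and 6 adjusted over the list alone, and 14 and 10 without that library; camera adjusted p = 0.19), with NCOA1 at 1.34 ± 0.07, KAT6B at 1.20 ± 0.08 and HDAC6 at -0.53 ± 0.06. Among bile acid genes CYP7A1 had 698 counts in DMSO and 2 in A-485, a 461-fold difference with a 95% counting interval of 127 to 3818, and CYP8B1 a 186-fold one (85.0 to 508). Both come from a list of bile acid and xenobiotic genes with 6 measured members, which did not all fall. CYP27A1 was lower too, at 79.1 to 80.4 CPM in A-485 against 296 to 303 in DMSO. CYP3A5 was higher, at 3.28 to 3.77 CPM in A-485 against 2.13 to 2.51 in DMSO.

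Unmapped reads made up 7.17% and 8.93% of the table in DMSO replicates 1 and 2, against 1.80 to 2.52% in the other 10 libraries.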
